A study of Mus musculus with 3 samples.

How the data were processed

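Gene expression was measured in left ventricle of male mice on 3 arrays, 1 each for Control, Iso and Iso+Insl6, and per the labels each array held a pool of 3 RNA samples. The authors deposited log2 expression values per probe set, made with RMA and affy 1.36.1 per the submitters' processing notes. RMA as published corrects background, sets the arrays to a common distribution and summarises the probes of a set by median polish; which of these steps ran with which settings is not given in the sources used here, nor is the array type, the genome build or the array date. The deposited values have 2 decimals and run from 0.44 to 12.45. The 3 arrays have the same median, 4.16, and their sorted values differ by at most 0.14 at any rank. Scanner files were not used here.

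Each probe set is named by an Entrez gene number, with 1 probe set per gene. Symbols were taken by that number from RefSeq's mouse gene table (assembly GRCm38.p6), which gave a symbol to 23740 of 25206 probe sets and none to 1466. The platform annotation listed 23185 of them with 1 symbol each and 0 with several, and all 23185 symbols were equal to RefSeq's. No coordinates are printed, since the build behind the probe sets is not known. All 3 columns were matched to their samples by label, and 0 columns were left unmatched.

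Differences were taken on the log2 scale as Iso minus Control, Iso+Insl6 minus Iso and Iso+Insl6 minus Control. The first and second are the comparisons the design text names. With 1 array per group no test of the conditions exists, and genes were counted by size alone, at least 1.5-fold (log2 0.585) in either direction, among genes at or above the background of 4.16 (the median of all values) on the higher array. The number of arrays limits the precision, and pooling hides the spread between mice. As a view of differences near background, genes past 1.5-fold were counted among 1404 genes of the olfactory, vomeronasal and keratin-associated families, whose 95th percentile level was 3.71, with exact binomial 95% intervals. Those above background were chosen on the array that is not compared, since a choice on the arrays compared favours large differences, and set beside the 20 other genes nearest in level to each; this choice was made after the data had been seen.

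Before the data were examined, 44 gene lists of heart pathways and cell types were fixed with 829 entries, of which 806, or 774 different genes, were measured. For each list the median difference, its 95% interval over members from order statistics, and the mean were computed. Each median and mean was placed among 10000 random lists of the same size, matched on mean level in 20 bins, as a description of these arrays. A list outside percentiles 2.5 to 97.5 was called outside the central 95%. Genes are not replicates, and these percentiles are not p-values. Another 12 lists were written after the rankings had been seen: 4 of liver genes that leave out every gene seen there, acute phase, kidney, lung, pancreas, CREB target genes, 2 arms of the clock, and the liver genes seen in the rankings, which were never used as a test. Kap of the kidney list and Scgb1a1 of the lung list had been seen. The liver genes left out of some counts were the liver lists and gene families named after liver products, 290 in all.

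The rule for named genes was fixed in advance: the 12 largest differences in each direction per comparison among genes above background, up to 4 members per list and any member at 1.5-fold, a short list of heart failure and INSL6 genes, and for movement back the 10 largest that lay at least 0.5 of the way back and the 5 largest that did not. Predicted genes, olfactory and vomeronasal receptors, antigen receptor segments and small RNAs were counted but not named. A few genes that the rule takes are not reported here, though they stay in the counts and list summaries. Genes named outside the rule, namely Hp, Pon1, Fgl1, Serpina3n, Sprr1a, Ahnak2, Fam107a and members of the added lists, were chosen after their values were seen.

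Movement back toward Control was set beside 100 simulations in which 3 arrays per gene drew independent noise around the gene's mean from the residuals of genes of similar level; these residuals hold real differences too. The counting and list steps were tested on simulated data for Iso+Insl6 against Control, with 23740 genes and 200 planted differences. Of 50 planted genes each, 37 were found at a planted 1.5-fold, 50 at 2-fold, 50 at 4-fold and 50 at 0.25-fold, 12 of 12183 unchanged genes passed 1.5-fold, and 11 of 200 random lists lay outside the central 95%. The noise in this test left out the most extreme residuals at each level. The count of 12 may therefore be too low and gives no false-call rate for the real arrays. All planted genes lay well above background, and the random lists were scored by mean, not by median.

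Alternatives were a 2-fold threshold, no filter on level, a filter above the silent families, cyclic loess between arrays, a new quantile normalization, centring each array on its genes above background, list means, lists without their largest member or without members below background, random lists not matched on level, and any movement back. Counts without liver genes, without clock genes, and with levels below background set to 4.16 were added after seeing the data, as were the alternatives for lists and named genes in Iso+Insl6 against Control. Genes were ranked by the listed values; for a gene below background on the lower array, the fold given is a lower bound, from the higher level minus 4.16. The software was R 4.3.3 with limma 3.58.1 for the normalizations, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.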

Results

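The series measured gene expression in the left ventricle of male C57BL/6N mice aged 8 to 12 weeks on 3 arrays. The Control array held RNA from mice that carried a vehicle pump and received saline. The Iso array came from mice with a vehicle pump that received isoproterenol, a beta-adrenergic agonist used to bring on cardiac injury, at 50 mg/kg per day for 11 days. For the Iso+Insl6 array the pump delivered INSL6, a peptide of the insulin and relaxin family, at 50 to 70 nmol/kg per day under the skin beside the same isoproterenol. Ventricles were taken at day 14, and each array was hybridised with a pool of 3 RNA samples. With 1 array per group there are no replicates, so no difference below has an error between animals and no p-value is given. Each array listed 25206 probe sets as log2 values with a median of 4.16, which served as the background level. Values on the 3 arrays ran from 0.44 to 12.45. Pearson's r across all probe sets, which are not independent replicates, was 0.997 between Control and Iso, 0.995 between Iso and Iso+Insl6 and 0.995 between Control and Iso+Insl6. A log2 difference of 1 is a 2-fold difference, and "higher" and "lower" describe the arrays. Where the lower of the levels compared lay below background, a fold is given as a lower bound against 4.16, and a log2 difference of such a gene is that of the listed values.

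The first comparison in the design, Iso against Control, asks what isoproterenol does to the normal ventricle. With predicted genes, olfactory and vomeronasal receptors, antigen receptor segments and small RNAs left aside, the largest difference was in the circadian clock gene Arntl. This activator, which pairs with Clock, stood at 7.07 on the Control array and 4.11 on the Iso array, a listed difference of -2.96. As 4.11 lies below background, Arntl was at least 7.52-fold lower. Its partners Npas2 (-1.22) and Clock (-0.62) were also lower, while the output gene Dbp was 4.11-fold higher at 9.46 against 7.42. The repressors Ciart (1.60), Per3 (1.53), Per2 (1.24), Bhlhe41 (1.24) and Per1 (1.02) were higher on the Iso array. Of the 18 clock genes measured, 8 were at least 1.5-fold higher and 3 at least 1.5-fold lower, with a median difference of 0.45 (95% interval over genes -0.04 to 1.24). That median lay above all 10000 random lists of genes with matched levels. The Iso+Insl6 array stood near these levels, with Arntl at 4.08 and Dbp at 9.38. No clock gene differed 1.5-fold between Iso and Iso+Insl6, and Npas2 differed most, by 0.43. The hour at which each heart was taken is not given in the sources used here.

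**Figure D1:**
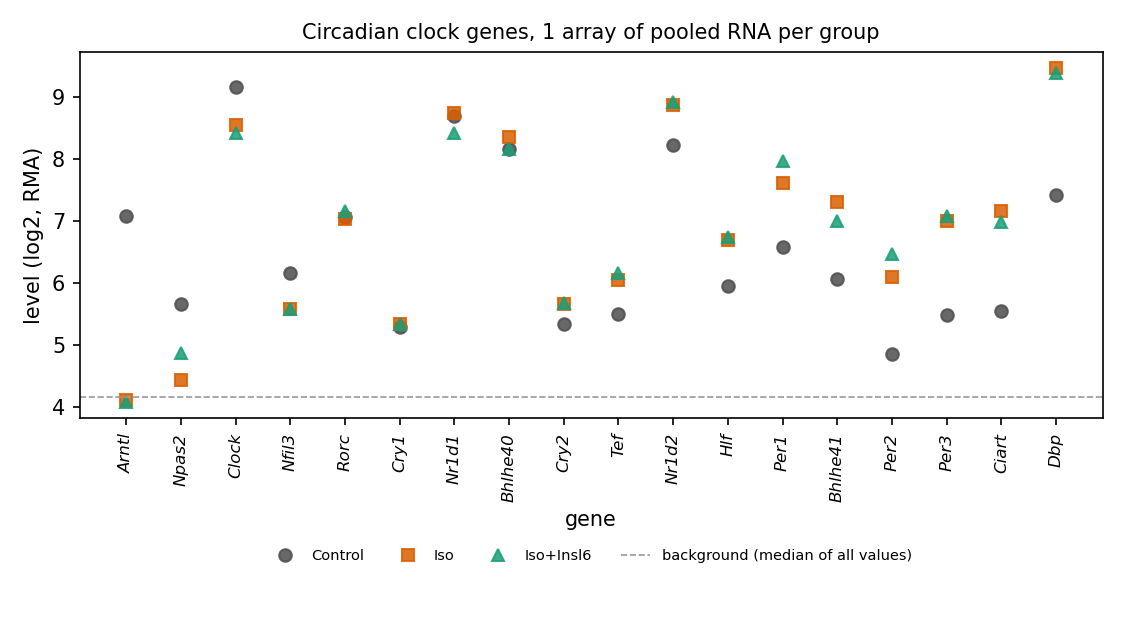
Levels (y axis, log2) of the 18 circadian clock genes (x axis) on the Control, Iso and Iso+Insl6 arrays, 1 array per group, with the background level of 4.16 as a dashed line. Arntl stands at 7.07 on Control, 4.11 on Iso and 4.08 on Iso+Insl6, and Dbp stands at 7.42, 9.46 and 9.38.

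Among genes not on the clock list, Cidea, a lipid droplet protein of fat cells (1.39), was highest on the Iso array relative to Control. Then came the cell cycle kinase Wee1 (1.28), the zinc finger gene Zfp738 (1.22), the joint and pericardial lubricant Prg4 (1.08) and the metallothionein Mt2 (1.07). The pseudogene Gapdh-ps15 (1.05) and Ceacam2 (1.03) followed. Whether any of these genes follow the clock was not tested. The lowest were Fam124b (-2.28), the fatty acid binding protein Fabp7 (-1.61), Tspan18 (-1.42), Trp53i11 (-1.34) and Pgam1, a glycolytic enzyme (-1.30). Several of the lowest are secreted or organ-restricted products of other tissues: the serum amyloids Saa2 (-2.21), Saa1 (-1.61) and Saa4 (-1.29), the acute phase protein Orm2 (-1.66) and the kidney androgen-regulated protein Kap (-1.38). All 5 genes stood above their Control levels on the Iso+Insl6 array. Zfp738 and Ceacam2 lay below background on Control, and Fam124b, Fabp7, Pgam1, Saa1, Saa4 and Orm2 on Iso. Against background Saa1 was at least 2.69-fold, Pgam1 at least 2.23-fold and Fam124b at least 2.17-fold lower, while the bounds for Fabp7 (1.37-fold), Orm2 (1.26-fold) and Saa4 (1.03-fold) did not reach 1.5-fold.

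Among cardiac stress genes the array gave a mixed picture. Ankrd1, a titin-bound protein of stressed muscle, was 1.74-fold higher (12.21 against 11.41) and the LIM protein Fhl1 1.77-fold higher, while the calcineurin inhibitor Rcan1 (-0.77) and the natriuretic peptide Nppb (-0.59) were lower. Nppa differed by 0.20, skeletal actin Acta1 by 0.43 and beta myosin heavy chain Myh7 by -0.21. The list of 19 stress genes had a median of 0.00 (95% interval -0.21 to 0.20). No gene of the 19 contractile and calcium handling genes reached 1.5-fold, with Myh6 at 11.91 on both arrays, Atp2a2 at 12.14 and 12.13, and Slc8a1 furthest up at 0.32. Ion channel genes had a median of 0.00 and ran from Kcnv2 (-0.58) to Kcne1 (0.46), and beta-adrenergic and cAMP pathway genes a median of 0.00 with none at 1.5-fold, Adrb1 differing by -0.15. In the renin-angiotensin and natriuretic peptide list, Nppb alone reached 1.5-fold and the median was 0.00.

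Matrix genes leaned upward by small amounts. Col14a1, a fibril-associated collagen, was 1.52-fold higher, and Lum (0.49), the fibroblast matrix protein Postn (0.42), Col3a1 (0.40) and Col1a2 (0.29) were higher by less, while elastin, Eln, was lower by -0.88. Col1a1 and Fn1 had the same values on both arrays. Over the 41 collagens and other matrix genes 19 were higher, 7 lower and 15 the same, with a median of 0.00 and a mean of 0.06 that lay at percentile 99.4 of matched random lists. Fibroblast markers had a median of 0.04 and a mean of 0.11, both outside the central 95% of random lists, led by Pi16 (0.61). Collagen processing genes (mean 0.00) and TGF-beta pathway genes (mean -0.005) had medians of 0.00 and no member at 1.5-fold, and Tgfb1 differed by -0.03 while Tgfb2, Tgfb3 and Ctgf, listed as Ccn2, did not differ. Matrix proteases and inhibitors had a mean of -0.07, with Mmp14 at -0.74 and Timp3 at 0.57; Timp1 stood at 3.87 and Spp1 at 3.69 or less on every array, below background.

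**Figure D2:**
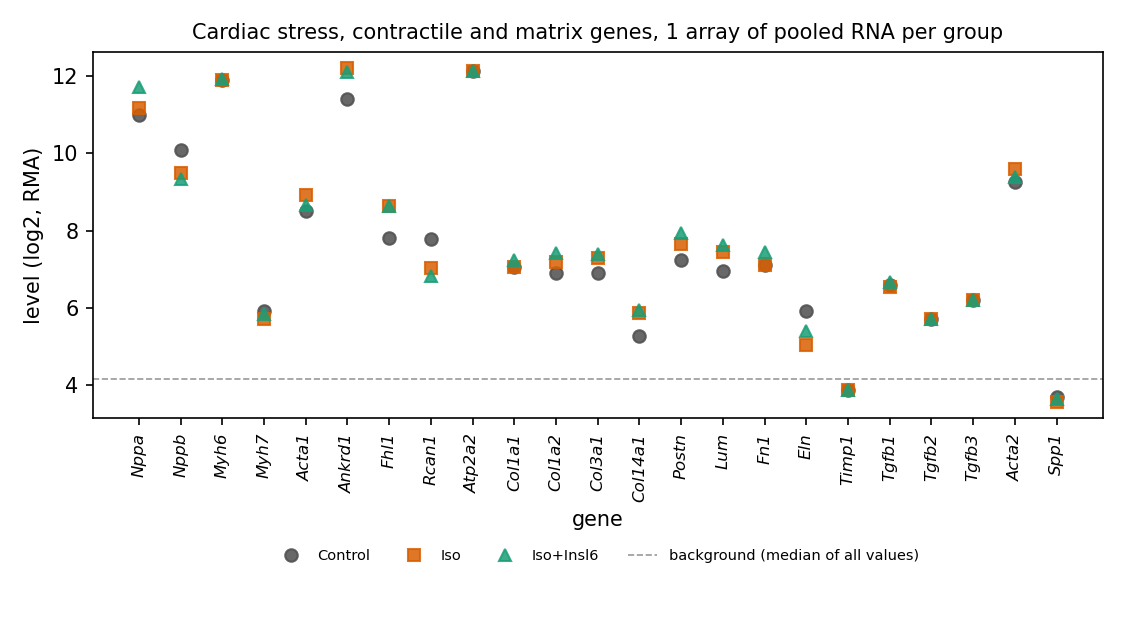
Levels (y axis, log2) of cardiac stress, contractile and matrix genes (x axis) on the Control, Iso and Iso+Insl6 arrays, 1 array per group, with the background level of 4.16 as a dashed line. Ankrd1 stands at 11.41, 12.21 and 12.10, Nppb at 10.08, 9.49 and 9.35, and Postn at 7.24, 7.66 and 7.93.

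Markers of most other cell types had medians of 0.00. Smooth muscle and pericyte markers (mean 0.02, Acta2 at 0.35), neutrophil markers (mean 0.00), T and NK cell markers (-0.03), B cell and plasma cell markers (0.00), mast cell markers (0.00), mesothelial and epicardial markers (-0.03), atrial and conduction markers (0.04) and skeletal muscle markers (-0.10) had no member at 1.5-fold. Most of these cell types were barely detected, with 0 of 12 neutrophil, 2 of 14 T and NK cell, 3 of 11 B cell, 2 of 8 mast cell, 3 of 9 mesothelial and 1 of 10 skeletal muscle markers above background, so their lists say little about those cells. Macrophage markers had a mean of 0.03, with galectin Lgals3 1.64-fold higher and Adgre1 at 4.93 on all arrays. Of the Schwann cell and neuronal markers (mean 0.06) only Tubb3 (0.68), which lies below background, passed 1.5-fold, and of the 5 erythroid genes measured (mean 0.15) only the globin Hbb-b1 (0.59). Endothelial markers were lower, with a median of -0.04, a mean of -0.10 and the VEGF receptor Kdr 1.53-fold lower. Adipocyte markers had a median of 0.02 and a mean of 0.14, with Cidea far above the rest. Only 5 of 12 lay above background, and Adipoq, Lep and Plin1 did not on any array, so this list says little about fat cells.

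Inflammatory genes were not higher as a group. Cytokines and chemokines had a median of 0.00 and a mean of -0.05, with Il33 at 0.66, Ccl6 at -0.72 and Ccl2 at -0.52, and Il6 lay at 1.43 on every array. Interferon response genes (mean -0.03, Isg15 at -0.61 but below background) and complement genes (mean -0.09, C6 at -0.52) also had medians of 0.00. Antigen presentation genes were lower, with a median of -0.02 and a mean of -0.17, through the class II genes H2-Aa (-0.75), H2-Ab1 (-0.50) and Cd74 (-0.50).

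Apart from the clock list, the clearest joint shift was in fatty acid oxidation genes. Harvest hours are not given, so a difference in hour was not separated from isoproterenol here either. Of 31 genes measured 23 were lower and 2 higher, with a median of -0.10 (95% interval -0.20 to -0.04) that lay below all 10000 random lists, and a mean of -0.22. The lowest were Pdk4, the kinase that holds back pyruvate oxidation (2.31-fold lower), the lipase inhibitor Angptl4 (at least 1.79-fold lower) and the mitochondrial carrier Ucp3 (1.78-fold lower). Genes of the TCA cycle (mean 0.02) and of oxidative phosphorylation (mean -0.004) had medians of 0.00 and no member at 1.5-fold. The glycolysis median was 0.02 but its mean was -0.02, since Pgam1 alone was far lower. Glucocorticoid and fasting responsive genes went both ways, with 8 of 16 higher and 8 lower, of which 2 and 5 by at least 1.5-fold (lower: Pdk4, Angptl4, Cdkn1a at -1.12, Ddit4 at 4.73 against 5.73, and Sgk1 at -0.61), a median of -0.04 and a mean of -0.18; the median turned to 0.04 without Pdk4.

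Protein folding genes were lower. The unfolded protein response list had a median of -0.12 and a mean of -0.14, with Manf 1.57-fold lower, the chaperone Hspa5 at -0.49 and Dnajc3 at -0.48. Heat shock genes had a median of -0.13, with Hsph1 at -0.52. The angiogenesis and hypoxia list had a median of -0.02 and a mean of -0.15, led by the peptide Apln (1.80-fold lower) and the oxygen sensor Egln3 (1.71-fold lower), with Vegfa at -0.48. Further lists had medians of 0.00: ATF4 and amino acid response genes (mean -0.12, with Ddit4 and Nupr1 lower), oxidative stress response genes (mean 0.10, Mt2 highest), cell death genes (mean -0.09, Cdkn1a lowest), cell cycle genes (mean -0.08, Ccnb1 at -0.73 and Uhrf1 at 0.61) and immediate early genes (mean -0.06, Dusp1 at -0.57). Cytosolic ribosomal protein genes (mean -0.06) held Rpl10a (-1.10) and Rps2 (-0.74), both below background. The sex check list had a median of 0.00, with Ddx3y at 8.22 or above and Xist at 2.82 on every array, in mice the labels give as male. Relaxin family ligands and receptors had a median of 0.09, but every member lay below background, with Insl6 at 1.89, Rxfp1 at 1.93 and Rxfp2 at 1.64 on all 3 arrays.

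In all, 105 genes were at least 1.5-fold higher and 128 at least 1.5-fold lower on the Iso array, out of 12415 above background on either array. At 2-fold the counts were 19 and 32. Of 44 lists, 12 medians and 16 means lay outside the central 95% of random lists, 10 of them by both. Random draws of genes would give 2.2, but genes of a list can move together and lists share genes, so this sets no test. Of 1404 genes from families that heart does not use (olfactory and vomeronasal receptors, keratin-associated proteins), 48 passed 1.5-fold at any level, 3.42%. Of the 41 that lay above background on the Iso+Insl6 array, which is not part of this comparison, 5 did, 12.2% (exact 95% interval 4.08 to 26.2), against 2.15% of 650 other genes of like level there. On a pair of arrays at least 60.9% of probe sets had identical values, so a list median of a few hundredths can lie at an extreme percentile.

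The second comparison, Iso+Insl6 against Iso, asks how the isoproterenol-treated ventricle differs when INSL6 is infused. The largest differences were in genes made in liver. The cytochromes Cyp2e1 (9.13-fold), Cyp3a41b (at least 5.24-fold) and Cyp2c50 (at least 1.66-fold), the protease inhibitors Serpina1d (8.34-fold), Serpina1e (8.00-fold) and Serpina1c (6.92-fold), tyrosine aminotransferase Tat (8.28-fold), the vitamin D binding protein Gc (7.21-fold), Mug1 (6.96-fold), Ces1c (at least 6.59-fold), carbonic anhydrase Car3 (at least 6.23-fold) and urate oxidase Uox (at least 4.53-fold) had the largest listed differences. Albumin, Alb, stood at 8.78, 8.97 and 11.12 on the Control, Iso and Iso+Insl6 arrays. Of 4 lists of liver genes not seen in those rankings, written afterwards, 2 were higher and 2 were not. Of 34 plasma protein genes 22 were at least 1.5-fold higher and none lower, with a median of 1.03 (95% interval 0.54 to 1.43) and Fgb highest at 2.13. Of 37 liver enzyme and transporter genes 19 were at least 1.5-fold higher, with a median of 0.60 (0.20 to 1.25). The 10 liver transcription factors and the 11 Kupffer and sinusoid genes had medians of 0.00 and no member at 1.5-fold. On the Control array 16 of the plasma protein genes and 14 of the enzyme genes were already above background.

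**Figure D3:**
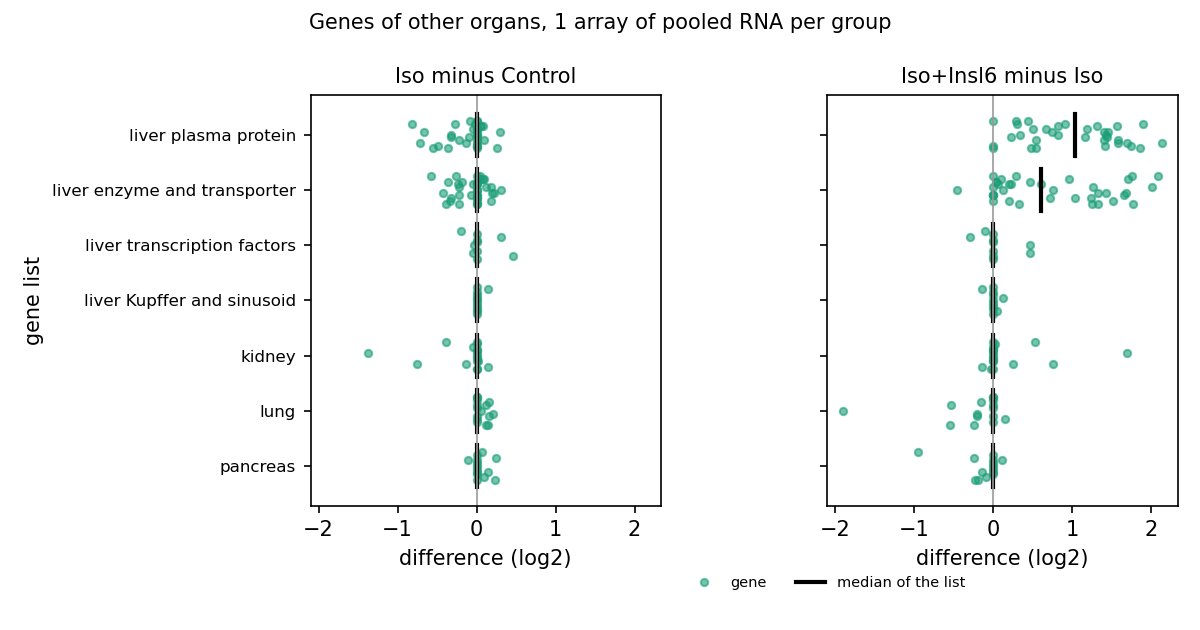
Log2 differences (x axis) of genes in lists for liver, kidney, lung and pancreas (y axis), Iso minus Control on the left and Iso+Insl6 minus Iso on the right, with 1 point per gene and a black bar at each list's median. The liver plasma protein and liver enzyme medians lie at 1.03 and 0.60 on the right, and the other 5 medians there at 0.00.

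Predicted genes, olfactory and vomeronasal receptors, antigen receptor segments and small RNAs were left unnamed, and 19 of them were passed over among the lowest here. The 12 lowest named on the Iso+Insl6 array were the airway secretory gene Scgb1a1 (-1.90), the class I gene H2-Q7 (-1.89), the ribosomal protein genes Rpl23a (-1.19) and Rpl19 (-1.07), Unc93a (-1.06), the heat shock gene Hspa1a (-1.05), Snrpn (-1.04), Krt15 (-0.84), Snrpc (-0.84), Defa30 (-0.81), Fsbp (-0.80) and Ifna5 (-0.79). All but Snrpc and Ifna5 lay at 5.96 or less on the Iso array. On the Iso+Insl6 array 8 of the 12 lay below background, where Scgb1a1 was at least 3.48-fold, H2-Q7 at least 1.93-fold and Fsbp at least 1.64-fold lower, and Rpl19, Hspa1a, Snrpn, Krt15 and Defa30 had bounds under 1.5-fold.

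Genes of heart muscle and matrix differed little. No cardiac stress gene reached 1.5-fold: Nppa was higher by 0.53 and Acta1 lower by -0.27, while Ankrd1 (-0.11), Nppb (-0.14) and Myh7 (0.13) differed less, and the list median was 0.00 (95% interval -0.11 to 0.06). Contractile and calcium handling genes had a median of 0.00 and a mean of -0.03. Of 41 matrix genes 20 were higher, 7 lower and 14 the same, none at 1.5-fold, with a mean of 0.05: Eln was at 0.36, Fn1 at 0.34, Postn at 0.27, Col1a2 at 0.22, Col1a1 at 0.16 and Col3a1 at 0.10. Col14a1, Lum, Postn, Col3a1 and Col1a2, named above as higher on Iso than on Control, did not stand lower on the Iso+Insl6 array. The fibroblast marker Pi16 (-0.28) and the smooth muscle gene Acta2 (-0.20), also named above as higher on Iso, did stand lower there. Of 11 smooth muscle and pericyte markers 4 were higher and 3 lower. TGF-beta pathway genes (mean 0.01, Tgfb1 at 0.12) and collagen processing genes (mean 0.01) had no member at 1.5-fold, and in the protease list only the inhibitor Timp4 (0.76) did. Of 15 fibroblast markers 10 were higher and 3 lower. Their median was 0.03, which turned to -0.01 when arrays were centred on genes above background.

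Glucocorticoid and fasting responsive genes were the fixed list with the largest shift. Of 16 measured 15 were higher and none lower, 5 at least 1.5-fold, with a median of 0.36 (95% interval 0.20 to 1.03) above all 10000 random lists. Among those 5 were the mTOR inhibitor Ddit4 (1.22), the transcription factor Zbtb16 (1.14), the glucocorticoid receptor chaperone Fkbp5 (1.03) and lipocalin Lcn2 (0.81). No member of this list is among the liver genes counted here, though liver expresses such genes too. Pck1, a glucose-forming enzyme of liver and fat, was higher by 1.93 and, together with Scd1 (1.07), raised the mean of the adipocyte list to 0.21. Complement genes had a mean of 0.21, with C3 at 8.97 against 8.12. C6 (0.87) and C2 (0.80) add to that mean, but C6 was at least 1.34-fold higher against background and C2 lay below background on every array. Complement proteins of plasma are made in liver, and the liver plasma protein list above moved the same way, with a median of 1.03; none of the complement list is among the liver genes counted here. The complement median of 0.03, like those of the ion channel (0.02), oxidative stress response (0.01) and heat shock (0.03) lists, turned below 0 under the same centring, and the heat shock mean was -0.03.

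Some lists were lower again. Antigen presentation genes had a median of -0.03 and a mean of -0.08, with H2-D1 at -0.25, and angiogenesis and hypoxia genes a median of -0.005 and a mean of -0.09, with Egln3 at -0.53 and Apln at -0.35. The relaxin family median of -0.12 rests on genes below background. Clock genes differed little, with a median of 0.005 and none at 1.5-fold, Npas2 being furthest up at 0.43. The fatty acid oxidation median was 0.00 and its mean 0.09, with Pdk4 at 0.13 and Angptl4 at 0.37. ATF4 and amino acid response genes had a mean of 0.14 with Ddit4, Cth (0.80) and Nupr1 (0.71) higher, and the glycolysis list held Pgam1 at 1.06. Macrophage markers (mean 0.00), cytokines and chemokines (0.02) and interferon response genes (-0.03) had no member at 1.5-fold.

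In this comparison 185 genes were at least 1.5-fold higher and 63 at least 1.5-fold lower, of 12457 above background, and 122 and 15 at 2-fold. With levels below background set to 4.16, which was added after seeing the data, 160 were higher and 35 lower. Liver genes made up 95 of the 185, 51.4%, and 83 of the 122, 68.0%; without them the counts were 90 and 62. The set of 290 liver genes left out was partly chosen from these rankings, and other genes abundant in liver, among them Hp (2.09), Pon1 (1.97) and Fgl1 (1.44), remain in the 90. Of 44 lists, 9 medians and 6 means lay outside the central 95% of random lists, 5 by both.

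The design also lets both comparisons be joined, to ask whether genes that differed on Iso lay back in the direction of Control when INSL6 was given. Of the 233 genes at least 1.5-fold different on Iso, 91 lay at least 0.5 of the way back to Control on the Iso+Insl6 array, 39.1% (exact 95% interval 32.8 to 45.6). This count has no upper limit, so it includes genes that passed Control and ended further from it on the other side. Both differences hold the Iso array, which by itself gives movement back. A set of 100 simulations gave all 3 arrays equal independent noise, drawn from residuals that hold real differences too. There the share was 50.4% on average, from 41.6% to 57.3%. Across 12513 genes the differences correlated at -0.342, against -0.501 in the simulations (-0.554 to -0.438), with a covariance of -0.0146 against -0.0238. The observed share lay below the lowest simulated one, though its interval reaches into their range. Equal noise sets the simulated share and correlation in advance, and the real arrays did not differ equally. Above background the standard deviation of differences was 0.179 for Iso against Control and 0.237 for Iso+Insl6 against Iso. It was 0.244 for Iso+Insl6 against Control. The simulations left this out, so the gap to them decides nothing about movement back. Among the kinds of gene named here, those furthest from Control that lay back were Saa2, Orm2, Saa1, Kap, Pgam1, Saa4, the fatty acid transporter Slc27a2, Serpina1e, Gapdh-ps15 and Ddit4. On the Control, Iso and Iso+Insl6 arrays Saa2 stood at 6.69, 4.48 and 6.79, so it ended near Control. Slc27a2 (5.33, 4.18 and 6.89) and Serpina1e (6.46, 5.35 and 8.35) passed Control and ended further from it than on Iso. Saa4 differed from Control by -1.29 on Iso and by 1.22 on Iso+Insl6, nearly as far on the other side. The rest of those named ended nearer to Control than on Iso. Liver genes were 15 of the 91, and without liver genes 76 of 215 lay back, 35.3%. Among the kinds of gene named, those furthest from Control that did not lie back were Arntl, Fam124b, Dbp, Fabp7 and Ciart.

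Iso+Insl6 against Control, which the design text does not name, shares no array of isoproterenol alone. It reuses the Control and Iso+Insl6 arrays of the other comparisons, so what repeats here is no independent support. Liver genes led again, with Cyp2e1 9.58-fold and Cyp3a41b at least 5.24-fold higher, followed after their removal by Dbp (1.96), the epithelial gene Sprr1a (1.87), Car3 (1.84) and Pon1 (1.84). Arntl (-2.99), Fam124b (-2.02), Scgb1a1 (-1.84) and Trp53i11 (-1.52) were lowest among the kinds of gene named, with 2 genes of other kinds passed over in that ranking. Sprr1a and Pon1 lay below background on Control, and Arntl, Fam124b and Scgb1a1 on Iso+Insl6. Matrix genes had a median of 0.01 and a mean of 0.11, both outside the central 95%, though centring, tried here after seeing the data, turned the median to -0.01, with 4 of 41 at least 1.5-fold higher, among them Postn at 0.69 and Lum at 0.66, and Nppa was higher by 0.73. Fatty acid oxidation (median -0.10), unfolded protein response (-0.10), antigen presentation (-0.20), and angiogenesis and hypoxia genes (-0.11) were lower. Medians were higher for the clock list (0.51, 95% interval -0.28 to 1.38) and the glucocorticoid and fasting list (0.44, -0.27 to 0.92). Both of these lists went both ways, with 9 and 7 members at least 1.5-fold higher and 3 in each at least 1.5-fold lower. Here 244 genes were at least 1.5-fold higher and 98 lower of 12420, or 152 and 98 without liver genes, and 11 list medians lay outside the central 95%.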

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

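Counts without liver or clock genes, and with levels below background set to it, and all alternatives for lists and named genes in Iso+Insl6 against Control, were added after the data had been seen; the other alternatives were planned. Of the counts and shares, 57 stayed within 1.5 times their value or inside the share's interval under the alternatives and 16 moved further. A 2-fold threshold gave 19 higher and 32 lower genes for Iso against Control, 122 and 15 for Iso+Insl6 against Iso, and 125 and 27 for Iso+Insl6 against Control, by its construction fewer. Without a filter on level, which lets in genes near the floor, there were 190 higher and 236 lower for Iso against Control, 313 and 190 for Iso+Insl6 against Iso, and 227 lower for Iso+Insl6 against Control. The silent family filter at 3.71, below the background of 4.16, gave 95 lower genes for Iso+Insl6 against Iso. Without liver genes 90 genes were higher for Iso+Insl6 against Iso and 152 for Iso+Insl6 against Control. Setting levels below background to it gave 35 lower genes for Iso+Insl6 against Iso, since such differences become lower bounds. Counting any movement back raised the share to 69.1%. Of the list medians 533 stayed inside their interval over members, 100 left it and 9 changed sign. Only lists outside the central 95% could count as a change of sign. Any other changes of sign are within the 533 and the 100. For Iso against Control the glycolysis mean was -0.0218, and the glucocorticoid and fasting median without Pdk4 was 0.04. For Iso+Insl6 against Iso, centring gave -0.01 for fibroblast markers, -0.01 for complement, -0.015 for ion channel, -0.03 for oxidative stress and -0.01 for heat shock genes, and the heat shock mean was -0.028. For Iso+Insl6 against Control, centring gave -0.01 for matrix genes. Centring shifts all genes by up to 0.04, larger than these medians. All 333 values of named genes kept their direction under the 3 normalizations. That outcome was nearly set in advance and says little about robustness. The median shift under these normalizations was at most 0.04 in size, while every one of these named differences was past 1.5-fold. Averaging several probe sets gave no value, since each gene has 1. No paired analysis was possible because each group has 1 array. Signal over background limits genes near 4.16, where silent families, chosen on the array not compared, passed 1.5-fold in 8.51% to 12.2% of cases. Those shares rest on 4 or 5 genes each, and other genes of like level passed in 2.15% to 3.45% of cases.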

Other observations

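All tests below but the liver RNA test were chosen, or their deciding value was changed, only after the result was seen; for the liver RNA test the prediction came first, though its gene lists were written after the rankings had been seen, and reading the kidney, lung and pancreas lists by mean as well as by median came after their medians.

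A few genes stood higher at each step from Control to Iso to Iso+Insl6. The acute phase protease inhibitor Serpina3n stood at 6.30, 7.27 and 8.12, the epithelial gene Sprr1a at 3.91, 4.66 and 5.78, Ahnak2 at 4.47, 5.28 and 5.93, Fam107a at 4.59, 5.23 and 5.98, and the alarmin Il33 at 4.27, 4.93 and 5.23. Timp3, a matrix-bound protease inhibitor, stood at 8.44, 9.01 and 9.38. The angiogenesis genes Egln3 (9.15, 8.38 and 7.85), Apln (5.45, 4.60 and 4.25) and Kdr (9.51, 8.90 and 8.69) stood lower at each step. These genes were picked after their values were seen, from 1 array per group.

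A few genes restricted to other organs differed as well. Kap of the kidney stood at 6.05, 4.67 and 6.36 on the Control, Iso and Iso+Insl6 arrays, and Scgb1a1 of the lung at 5.90, 5.96 and 4.06. Only 3 of 17 kidney, 5 of 15 lung and 3 of 14 pancreas genes lay above background for Iso+Insl6 against Iso. Their means in this comparison, 0.18, -0.24 and -0.12, lay outside the central 95% of random lists, but rest partly on genes below background on every array, such as Umod, Sftpb and Cela3b. The kidney and lung means also rest on Kap (1.69) and Scgb1a1 (-1.90), which had been seen before the lists were written. For Iso against Control, the liver plasma protein list had a mean of -0.13, the liver enzyme list -0.07, the liver transcription factors 0.05 and the Kupffer and sinusoid genes 0.01, with medians of 0.00. The plasma protein and enzyme means, at percentiles 0.02 and 1.79, lay outside the central 95%, so liver genes were lower on Iso than on Control by these means.

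A first pattern is the higher level of liver genes on the Iso+Insl6 array, where the 48 liver genes seen in the rankings had a median of 2.35 and 2 of the 4 lists of unseen liver genes were higher too. Liver tissue or liver RNA in the pool would raise such genes, and the lower of the medians of the plasma protein and enzyme lists was 0.60, past 1.5-fold. It was also expected to leave the kidney, lung and pancreas lists inside the central 95%. Their medians of 0.00 decide nothing, because most members lie below background and most probe sets are tied, and their means lay outside. The kidney and lung means hold Kap and Scgb1a1, the furthest members of those lists. Both genes had been seen before the lists were written, so these means decide little. Liver transcription factors and Kupffer and sinusoid genes also had medians of 0.00, but most lie near or below background, with 5 of 10 and 4 of 11 above it on the Iso+Insl6 array. An acute phase response in the heart alone would not raise liver enzymes. Their median of 0.60 has a 95% interval over genes of 0.20 to 1.25. However, the first form of this test was the acute phase median of 0.03 minus the enzyme median. It gave -0.575, with a bootstrap interval over genes from -1.24 to 0.40. By mean the acute phase list was higher too, at 0.485 with 4 of 12 genes at least 1.5-fold higher. The difference by mean was -0.263 (-0.699 to 0.232 over genes), so only an acute phase response as the whole cause is argued against. None of these intervals measures the spread between hearts. Liver RNA in the pool and an action of INSL6 on these genes in the ventricle cannot be told apart, because INSL6 was given in 1 pool only and the lists of other organs are too near background to show whether liver stands alone; the action of INSL6 was not tested.

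Clock genes make a second pattern, in which the Control array stands apart from both isoproterenol arrays. The 6 genes of the Arntl arm had a median of -0.60 and the 11 of the Per and Dbp arm 1.02 for Iso against Control, a difference of -1.62 between arms. The arms were written after these genes had been seen, so this value restates the pattern and neither adds to nor takes from a difference in clock phase at harvest. For Iso+Insl6 against Iso the arms had medians of 0.00 and 0.05. An acute cAMP signal at harvest would raise CREB target genes along with Per1, but their mean was -0.147 (bootstrap 95% interval over genes -0.30 to -0.027) and their median 0.00. That interval measures the spread among these genes, not between hearts. A phase shift by isoproterenol and a different hour of harvest cannot be told apart, because harvest hours are not given in the sources used here and each group is 1 pool.

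The third pattern is the share of probe sets with identical values at 2 decimals, 61.5% between Control and Iso, with 51.3% the same on all 3 arrays and 81.7% on at least 2. Rounding would make 2.40% of values the same at the observed spread, far fewer. Median polish, which RMA uses, could produce such ties: simulated probes with noise only gave a median of 58.4% over 10 settings, from 42.8% to 87.3% at 7 to 25 probes per set, but only 3.95% to 5.47% at 4 probes, and the number of probes per set is not known here. In those simulations a true log2 difference of 0.25 came out as 0.10 to 0.24 and one of 1 as 0.87 to 0.99. Identical values on a pair of arrays may therefore hide small differences, and no biological explanation of the ties was tested.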
